A study of Homo sapiens with 3 samples.

How the data were processed

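ChIP-seq for Fra-1, Fra-2 and input DNA was done in MDA-MB-231 cells grown in medium with 10% serum at 37°C, per the labels. The labels mention 2 independent replicates of each. Libraries were made with an Illumina ChIP kit and sequenced on a HiSeq instrument, per the labels' protocols. The submitters' processing notes name Bowtie2 and the genome build hg19, without a version or a role for the tool. The peak caller, its threshold, the use of the input and the way replicates were combined are not given in the sources used here.

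The deposited files hold other values than counts: the start and end of each peak as the authors called it, on a grid of 50 bp, with 1 list per antibody and no score, height or p-value. All 9998 Fra-1 starts and all 13003 Fra-2 starts lie 1 above a multiple of 50, so starts were read as 1-based, and positions are printed as the files give them. Peak ends on chromosome 1 reach 249240201, and no nuclear peak passes the end of its chromosome in GRCh37, the assembly behind hg19. Peaks on the mitochondrial chromosome (chromosome M) reach 16701 in both lists and were not part of this check. The input library was not used here. Depth is unknown, so precision is given by the number of peaks alone.

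The tests and 15 gene lists (301 entries, all matched to the annotation, 298 distinct) and 15 consensus motifs were fixed before the data were examined. The design foresaw a score per peak. As the lists hold none, width replaced it: the test of rank used width, the stricter threshold became peaks at least 200 bp wide, and the longer list was shortened to its widest peaks with ties broken at random. The width limit was thus set after the lists had been seen. The rule for named items was FOSL1, FOSL2 and HMGA1, then up to 4 members of each list with the widest Fra-1 peak within 100 kb, the 10 widest peaks of each list and the 5 widest found in 1 list only. Widest peaks outside repeat-like regions were added after the data were seen.

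Everything was computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and samtools 1.23.1, with GENCODE 44 lifted to GRCh37. Peaks sharing at least 1 bp were called shared. Chance overlap and position came from 1000 circular shifts within each chromosome with runs of N of at least 1000 bp taken out, or 200 shifts for alternative counts of genes. Motifs were sought on both strands within 100 bp of peak centres, with at most 1 control window per peak 5000 to 20000 bp away and in the same GC bin of 5 percentage points, and compared with two-sided Fisher exact tests. Promoters were within 1 kb of the TSS of a protein-coding transcript, and took precedence over coding exons, other exons and introns. Gene lists were compared with 10000 random lists matched on quintiles of local gene density. Benjamini-Hochberg adjustment ran over 15 motifs, 15 lists, 30 position tests or the chromosomes. Classes of peaks were also weighted to a common distribution of width or GC content, with intervals from 1000 bootstrap draws. Chromosome M was left out of sequence and annotation tests, because its reference sequence can differ between hg19 and GRCh37, and chromosome Y out of gene tests.

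Repeat-like regions were defined after the positions of the peaks had been seen: chromosomes Y and M, 1 Mb around assembly gaps of at least 1 Mb, and windows of 1000 bp to each side of a centre in which over 20% of 10-base words recur. In a further setting chosen after the data were seen, members of a gene list with a TSS within 200 kb of each other counted once. A first definition with a wider margin around gaps was dropped because it took in genes such as EGFR. Before the data were examined, other settings had been chosen: reciprocal overlap of 50%, centres within 500 bp, the upper part of each list by score, the longer list shortened to equal length by score, merged neighbours, other motif windows, promoters of 5 kb, genes within 10 kb or nearest only, no matching on density and clustering within 5 kb.

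The methods were tested on simulated data. With 49.9% of 9970 peaks planted as shared, 49.9% were found. Uniform positions gave a TGASTCA ratio to controls of 1.04. Of 200 draws of 15 lists of 20 genes without effect, placed in gene-dense regions, 1% had any list called with matching and 40.5% without. A list with over 90% of members near a peak was called in 87.5% of draws.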

Results

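Chromatin immunoprecipitation followed by sequencing (ChIP-seq) mapped the binding sites of Fra-1 and Fra-2 in MDA-MB-231 cells, an established human breast cancer line of the triple-negative, basal B type. Fra-1 and Fra-2, encoded by FOSL1 and FOSL2, are members of the Fos family and bind DNA as AP-1 dimers with Jun proteins. The series holds a Fra-1 sample, a Fra-2 sample and an input DNA sample, and its labels mention 2 independent replicates of each. One peak list per antibody was analysed here, and the input was not analysed here, so no value below has a spread between replicates. Intervals of shares are 95% exact binomial (Clopper-Pearson) and those of ratios are 95% log-normal; they cover counting error only and treat neighbouring peaks as independent. The Fra-1 list held 9998 peaks over 1811 kb and the Fra-2 list 13003 peaks over 2393 kb, with a median width of 150 bp in both. Read depth behind the peaks is unknown, and the lists carry no height or score.

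Peaks were not spread over unique sequence alone. Of the Fra-1 peaks, 1523 (15.2%, 14.5 to 16.0) lay in tandem repeats, within 1 Mb of an assembly gap of at least 1 Mb, or on chromosomes Y and M, and so did 1601 Fra-2 peaks (12.3%, 11.8 to 12.9). The densest window of the Fra-1 list, chromosome 10 from 42000001 to 43000000 (hg19), held 197 peaks. These regions are called repeat-like below. They were defined after the positions of the peaks had been seen, and 8475 Fra-1 and 11402 Fra-2 peaks lay outside them. Dense windows remained there: chromosome 2 from 133000001 to 134000000 still held 46 Fra-1 and 33 Fra-2 peaks. The definition may thus have missed some regions of this kind.

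The series asks which sites each protein occupies, so the first comparison was how far the lists coincide. Most Fra-1 peaks overlapped the Fra-2 list: 8039 Fra-1 peaks (80.4%, 79.6 to 81.2) shared at least 1 bp with a Fra-2 peak. In the longer Fra-2 list, 8015 peaks (61.6%, 60.8 to 62.5) shared sequence with a Fra-1 peak, which left 4988 peaks in the Fra-2 list only and 1959 in the Fra-1 list only. Shared peaks sat on the same spot, with a median distance of 25 bp between centres. In 1000 random circular shifts along each chromosome, a mean of 0.179% of Fra-1 peaks and 0.138% of Fra-2 peaks overlapped, with p = 0.001 for both (one-sided permutation test, the smallest p that 1000 shifts can give). Outside repeat-like regions 79.4% of Fra-1 and 59.1% of Fra-2 peaks were shared. Among repeat-like peaks alone the shares were higher, at 85.9% and 79.8%. Overlap beyond the circular shifts therefore does not by itself show that both proteins bind a site.

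Wide peaks were shared more often than narrow ones. Outside repeat-like regions the shared part of the Fra-1 list rose from 61.7% (59.6 to 63.7) of peaks 100 bp wide to 98.9% (97.7 to 99.6) of those at least 350 bp wide. In the Fra-2 list it rose from 34.6% (32.9 to 36.3) to 96.6%. A shared peak was wider than an unshared peak of the same list with a probability of 0.693 for Fra-1 and 0.699 for Fra-2 over all peaks, ties split evenly (two-sided permutation test, p = 1e-05 for both, the smallest that 100000 resamples can give). Width stood in for the peak score that the design had foreseen.

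**Figure D1:**
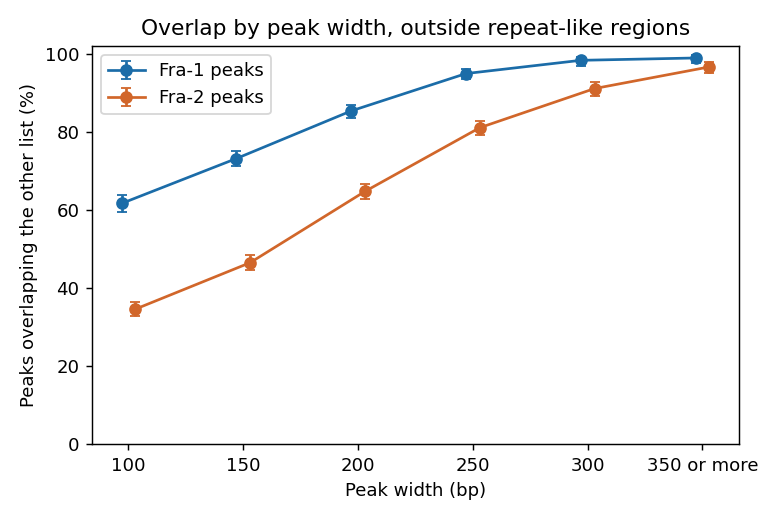
Percent of Fra-1 and Fra-2 peaks outside repeat-like regions that overlap a peak of the other list (vertical axis) by peak width in bp (horizontal axis), with 95% exact binomial intervals as bars. The share rises with width from 61.7% to 98.9% in the Fra-1 list and from 34.6% to 96.6% in the Fra-2 list.

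The AP-1 element TGASTCA (S is C or G) marked most peaks of both lists. It lay within 100 bp of the centre of 56.8% of nuclear Fra-1 peaks (55.8 to 57.7) and 67.5% of nuclear Fra-2 peaks (66.7 to 68.3), against 3.16% and 3.26% of control windows of matched GC content nearby. Outside repeat-like regions the shares were 65.6% and 75.6%, which were 19.3 times (17.2 to 21.7) and 21.5 times (19.5 to 23.7) those of the controls. In repeat-like regions they were 6.69% and 9.37%. Of 459778 copies of the element on the nuclear chromosomes, 1.57% lay in a Fra-1 peak and 2.29% in a Fra-2 peak.

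**Figure D2:**
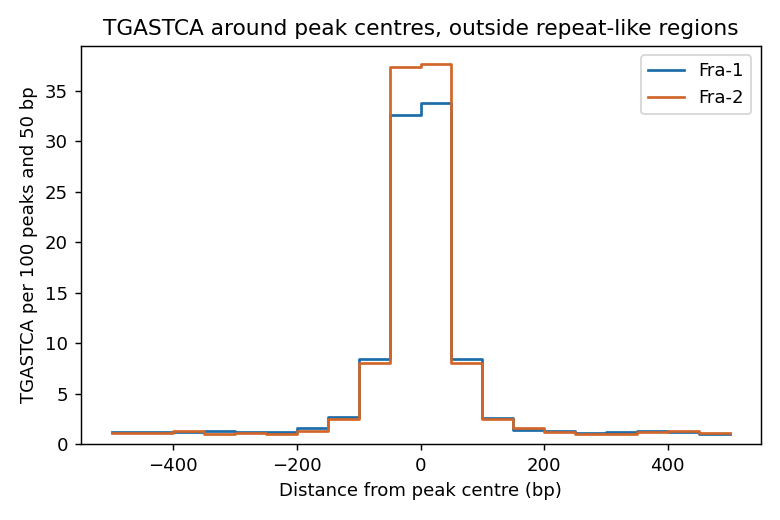
Number of TGASTCA elements per 100 peaks in each 50 bp bin (vertical axis) by distance from the peak centre in bp (horizontal axis), for Fra-1 and Fra-2 peaks outside repeat-like regions. Both lines peak in the bins next to the centre, at 33.8 elements per 100 peaks for Fra-1 and 37.6 for Fra-2, and lie near 1.05 and 1.09 in the last bin.

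Peaks found in a single list differed from each other in sequence. Outside repeat-like regions, 81.1% (80.0 to 82.2) of the 4667 Fra-2-only peaks held TGASTCA, against 43.4% (41.0 to 45.8) of the 1747 Fra-1-only peaks, a ratio of 0.535 for Fra-1-only over Fra-2-only (two-sided Fisher exact test, adjusted p = 5.22e-181 over 15 motifs). Shared peaks lay between, at 71.4% in the Fra-1 list and 71.7% in the Fra-2 list. The TEAD consensus GGAATGY, bound by the partners of the YAP and TAZ coactivators, went the other way, with 16.0% of Fra-1-only and 8.83% of Fra-2-only peaks (Fisher exact test, adjusted p = 1.65e-14). The RUNX consensus was in 6.30% of Fra-1-only and 3.77% of Fra-2-only peaks (Fisher exact test, adjusted p = 0.000117). The cyclic AMP response element TGACGTCA was rare, at 0.229% and 0.750% (Fisher exact test, adjusted p = 0.0439), and its difference did not hold when both classes were weighted to the same GC content (ratio of Fra-2-only to Fra-1-only 1.81, 0.783 to 12.1).

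**Figure D3:**
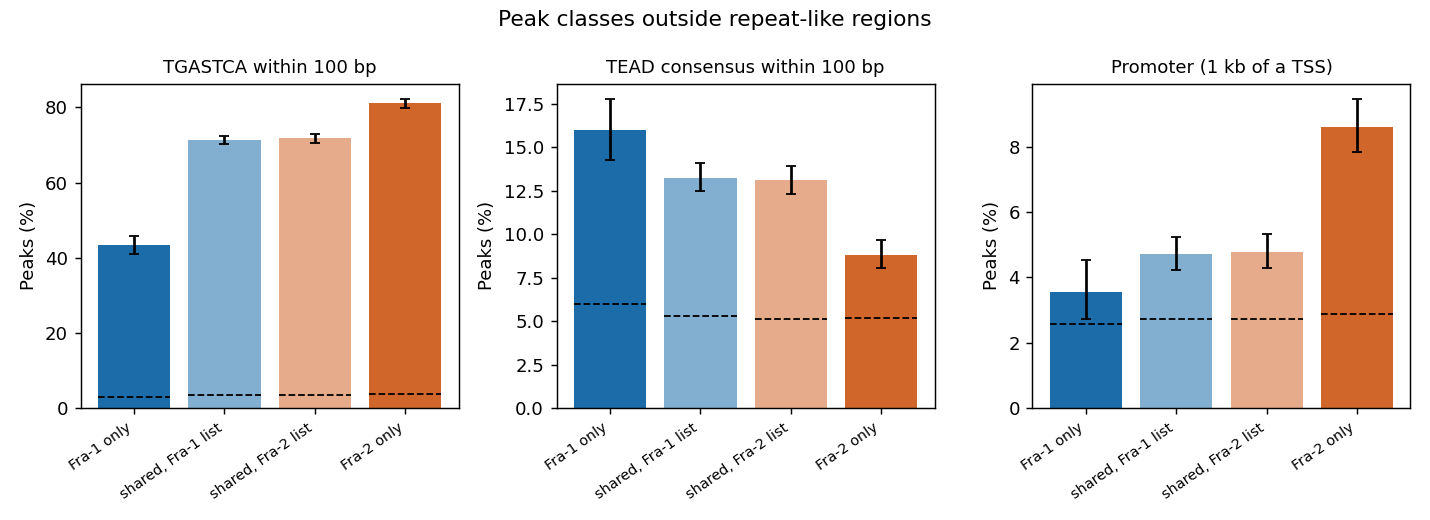
Percent of peaks outside repeat-like regions (vertical axes) with TGASTCA, with the TEAD consensus, and within 1 kb of a transcription start site, for Fra-1-only, shared and Fra-2-only peaks. Bars start at 0, error bars are 95% exact binomial intervals, and dashed lines are GC-matched controls (motifs) or the mean of circular shifts (promoters). Fra-2-only peaks have the highest TGASTCA share, 81.1%, and promoter share, 8.61%, and the lowest TEAD share, 8.83%.

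Other consensus sequences were also more frequent in peaks than in their controls. Outside repeat-like regions the TEAD consensus lay in 13.8% of Fra-1 peaks, 2.55 times the control share (2.29 to 2.83), and in 11.3% of Fra-2 peaks, 2.21 times (2.01 to 2.43). RUNX sites were 2.93 and 2.34 times and FOXA sites 2.58 and 2.94 times as frequent as in controls for Fra-1 and Fra-2. ETS sites, at 0.425% and 0.412% of peaks, were 2.69 and 2.28 times as frequent. The GATA consensus and the p53 decamer did not pass the test, with intervals of the ratio of 0.926 to 1.31 and 0.777 to 1.23 for Fra-1 and 0.909 to 1.26 and 0.806 to 1.23 for Fra-2. The E-box CAGGTG, bound by ZEB and SNAIL repressors, was less frequent than in controls, at 0.602 times (0.561 to 0.647) and 0.554 times (0.522 to 0.588). Rare sites followed suit in part: C/EBP sites, in 23 Fra-1 and 21 Fra-2 peaks, were 7.45 and 4.08 times as frequent as in controls and passed for both. NF-kB passed for Fra-1 (1.48 times, Fisher exact test, adjusted p = 0.0277; Fra-2 1.32 times, 0.0559). The cyclic AMP response element (4.13 times), the CTCF core (2.32 times) and SP/KLF sites (1.67 times) passed for Fra-2, and not for Fra-1 (2.43, 1.13 and 1.53 times). NFI sites lay in 5 and 9 peaks and the MAF element in 1 of each list, and neither passed.

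Most peaks lay away from promoters, and Fra-2 peaks reached promoters more often. Within 1 kb of the transcription start site (TSS) of a protein-coding gene lay 3.83% (3.46 to 4.23) of Fra-1 and 5.66% (5.27 to 6.07) of Fra-2 peaks, which were 1.43 and 2.04 times the mean of the circular shifts (one-sided permutation test, p = 0.001 for both, the smallest possible). The Fra-2-only peaks stood out, with 8.61% (7.82 to 9.46) at promoters outside repeat-like regions, against 3.55% (2.73 to 4.53) of Fra-1-only peaks (ratio of Fra-1-only to Fra-2-only 0.412, 0.317 to 0.535, Fisher exact test, adjusted p = 6.49e-13 over 30 tests). Weighted to the same GC content, the ratio of Fra-2-only to Fra-1-only promoter shares fell from 2.43 to 1.62 (bootstrap interval 1.29 to 2.12). Shared peaks had 4.71% and 4.78% at promoters in the Fra-1 and Fra-2 lists. Coding exons held 0.532% of Fra-1 and 0.670% of Fra-2 peaks, 0.506 and 0.620 times chance. Introns held 37.2% and 39.6% and intergenic sequence 57.2% and 52.6%. The excess of intergenic Fra-1 peaks over chance rested on repeat-like regions, since outside them 50.6% were intergenic, below the 52.4% of the shifts.

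At the genes of the factors themselves, both lists had peaks. FOSL1 (chromosome 11, 65659520 to 65668044, minus strand) had 6 Fra-1 and 4 Fra-2 peaks within 100 kb of a TSS. One pair, Fra-1 at 65666801 to 65666951 and Fra-2 at 65666751 to 65667001, lay inside the gene 0.983 kb from the TSS and held TGASTCA. Further pairs lay upstream. The nearest, from 65670651 to 65670951 in both lists, was 2.76 kb from the TSS and had no TGASTCA within 100 bp of its centre. Those at 65678951 to 65679301 and 65683201 to 65683551 in the Fra-1 list held TGASTCA but lay nearer to a TSS of C11orf68. FOSL2 (chromosome 2, 28615315 to 28640184, plus strand) had 6 Fra-1 and 8 Fra-2 peaks, with a Fra-1 peak at a TSS from 28615651 to 28615801 and another in an intron from 28632251 to 28632451. HMGA1 (chromosome 6, 34204650 to 34214008, plus strand), which encodes an architectural chromatin protein, had 3 peaks in each list, and all 3 were shared. The widest of them was centred in the last intron, reached into the last exon and spanned 750 bp in the Fra-1 list, from 34211901 to 34212651, and 700 bp in the Fra-2 list.

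**Figure D4:**
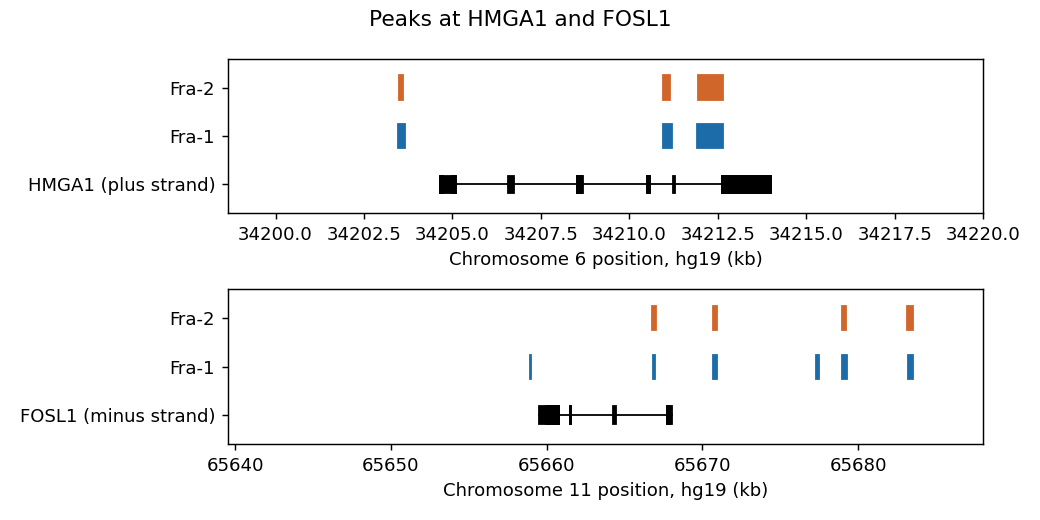
Fra-1 and Fra-2 peaks (coloured boxes) and exons (black boxes) at HMGA1 on chromosome 6 and FOSL1 on chromosome 11, drawn to scale against hg19 position in kb. All 3 peaks at HMGA1 are in both lists, and the widest, 750 bp in the Fra-1 list, ends inside the last exon.

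The widest peaks of both lists were on the mitochondrial chromosome, where Fra-1 peaks reached 3250 bp and Fra-2 peaks 8200 bp, followed by a repeat-like peak on chromosome 16 from 90061151 to 90062651 that was 1500 bp wide in both. Peak widths on the mitochondrial chromosome added up to 13450 bp for Fra-1 and 16000 bp for Fra-2, with ends not checked against its length. Whether they reflect binding was not tested, as the input was not analysed here. Outside repeat-like regions, the widest Fra-1 peaks were that of HMGA1 and one at the promoter of AXL, a receptor tyrosine kinase, on chromosome 19 from 41731501 to 41732251. The widest Fra-2-only peak lay in an intron of SMCO4 on chromosome 11 from 93275051 to 93275501. The widest Fra-1-only peaks were repeat-like, on chromosome 20 from 26188701 to 26189251 and on chromosome 21 from 9825351 to 9825851, and the widest outside was intergenic on chromosome 12 from 96861051 to 96861501.

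Many genes had a peak in reach. Of 19748 protein-coding genes, 8510 (43.1%) had a Fra-1 peak within 100 kb of a TSS and 11096 (56.2%) a Fra-2 peak, against means of 7246 and 8761 in 1000 circular shifts (one-sided permutation test, p = 0.001 for both, the smallest possible). Both kinds were near 7974 genes, Fra-1 alone near 536 and Fra-2 alone near 3122. MICAL2, which encodes an actin-regulating oxidoreductase, had 15 Fra-1 and 19 Fra-2 peaks outside repeat-like regions. CDC27, a gene of cell division, had 15 and 14, and no gene had more Fra-1 peaks. The pair was chosen after the values were seen. MYL4, on chromosome 17 like CDC27, had 14 and 13. Whether such counts reflect binding or dense regions that the repeat-like definition missed was not tested.

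Genes in 15 lists were tested for peaks within 100 kb against 10000 random lists of equal size and local gene density. Targets of YAP/TAZ and TEAD had peaks most often, near 21 of 23 members for Fra-1 and 23 of 23 for Fra-2, where chance gave 9.72 and 12.1 (adjusted p = 0.0015 for both, permutation test over 15 lists). Among them AXL had 4 peaks in each list, and CCN1, a matricellular growth regulator, had 3 and 5. Mesenchymal genes also passed for both factors, with 15 of 20 for Fra-1 (permutation test, adjusted p = 0.0129) and 18 of 20 for Fra-2 (adjusted p = 0.0045), where chance gave 8.40 and 10.5. TGFBI, an extracellular matrix protein, had peaks at its promoter in both lists. Cytokines and chemokines had peaks near 16 of 20 members for Fra-1 (permutation test, adjusted p = 0.0075) and 17 of 20 for Fra-2 (adjusted p = 0.0291). CCL20 had a 600 bp peak 4.64 kb from its TSS in both lists, and LIF had 6 Fra-1 and 7 Fra-2 peaks. The cytokine call was lost at 10 kb, with 4 members for Fra-1 at 2.21 times chance, no lower than at 100 kb (1.84 times), and 3 for Fra-2 at 1.02 times. Neighbours such as CXCL2 and CXCL3, MMP1, MMP3 and MMP10, or KRT14, KRT16 and KRT17 share peaks, so members are not independent. With 1 member per locus, a setting added after the data were seen, the luminal list no longer passed for Fra-2 (14 of 18, 1.45 times chance), while the AP-1 list passed for Fra-1 (13 of 18) and the basal list for Fra-2 (13 of 15).

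The remaining lists passed for a single factor or for neither, and the difference between the factors was not tested. Basal keratins and integrins had peaks near 15 of 20 for Fra-1 (permutation test, adjusted p = 0.0129) and 16 of 20 for Fra-2 (adjusted p = 0.0557), with a 500 bp Fra-1 peak 6.14 kb from ITGA3. The basal list passed for Fra-2 among peaks at least 200 bp wide (16 members against 7.63 by chance), with nearest TSS (14 members) and outside repeat-like regions (16 members). Proteases and matrix genes had 16 of 20 for Fra-1 (permutation test, adjusted p = 0.00675) and 14 of 20 for Fra-2 (adjusted p = 0.195), among them PLAU, the urokinase gene, with promoter peaks in both lists and 6 Fra-1 and 10 Fra-2 peaks. Genes of the EGFR, RAS and MAPK pathway had 15 of 24 (permutation test, adjusted p = 0.0852) and 19 of 24 (adjusted p = 0.027), with 10 peaks of each factor near EGFR and 10 and 12 near the phosphatase gene DUSP5. For Fra-1 this list passed within 10 kb (9 members against 2.21 by chance), with nearest TSS (14 members) and among peaks at least 200 bp wide (13 members). Luminal genes had 10 of 20 (permutation test, adjusted p = 0.473) and 16 of 20 (adjusted p = 0.0402), and ribosomal protein genes 15 of 24 (adjusted p = 0.105) and 20 of 24 (adjusted p = 0.0291). Among peaks at least 200 bp wide the protease list no longer passed for Fra-1 (9 members against 5.22 by chance) nor the luminal list for Fra-2 (12 members against 7.25), although the ratios to chance, 1.72 and 1.65, lay near those over all peaks, 1.87 and 1.47. Also, without matching on gene density neither the luminal nor the MAPK list passed for Fra-2, at ratios of 1.42 and 1.41 to chance, and with nearest TSS the luminal list did not (10 members against 6.46). The ribosomal call for Fra-2 was lost at 10 kb at a ratio to chance that was no lower (6 members, 1.65 times, against 1.42 times at 100 kb), and with nearest TSS at 5 members against 5.08 by chance.

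**Figure D5:**
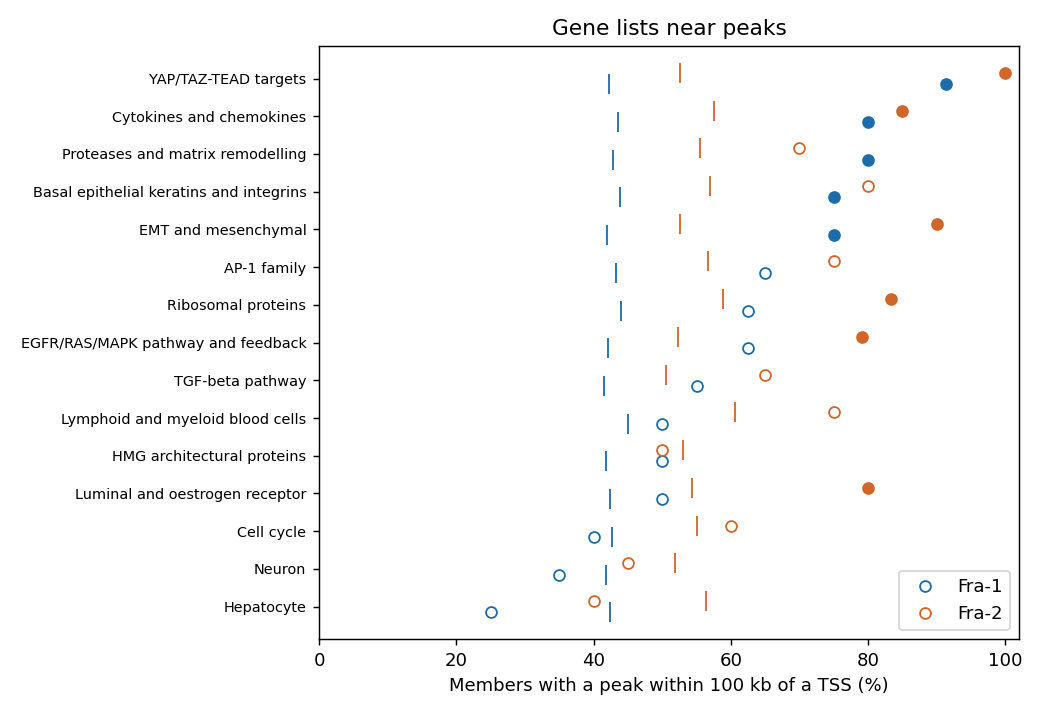
Percent of members of 15 gene lists with a peak within 100 kb of a TSS (horizontal axis) for Fra-1 and Fra-2. Filled circles pass an adjusted p of 0.05 for more members than chance, open circles do not, and vertical ticks mark the mean of matched random lists. Targets of YAP/TAZ and TEAD lie farthest to the right, at 91.3% for Fra-1 and 100% for Fra-2.

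Other lists passed for neither factor. The AP-1 family had peaks near 13 of 20 members for Fra-1 (permutation test, adjusted p = 0.0936) and 15 of 20 for Fra-2 (adjusted p = 0.136), with 5 Fra-1 and 6 Fra-2 peaks near JUN. Within 10 kb it passed for both, with 7 and 9 of 20 members. The TGF-beta pathway had 11 and 13 of 20, although SMAD3, which transmits its signal, had 12 Fra-1 and 14 Fra-2 peaks. Cell cycle genes had 8 and 12 of 20, and the HMG family 5 of 10 for each factor. Markers of other cell types had 5 and 8 of 20 (hepatocyte), 7 and 9 of 20 (neuron) and 10 and 15 of 20 (blood cells). No list had fewer members near peaks than chance at an adjusted p of 0.05.

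Peaks came in groups. A neighbour of the same list lay within 12 kb and 500 bp of 43.8% of Fra-1 and 44.3% of Fra-2 peaks, against 9.43% and 12.2% for uniform positions (one-sided permutation test, p = 0.001 for both, the smallest possible), and outside repeat-like regions the shares were 35.2% and 37.6%. Outside repeat-like regions chromosome 20 held 5.14 Fra-1 and 7.60 Fra-2 peaks per Mb and chromosome X 0.516 of each. Copy number in this aneuploid line may change how many peaks are called and was not examined, so these densities do not measure binding preference. Of the peaks of both lists together, 43.5% were Fra-1 peaks. The mitochondrial chromosome alone departed from this in the exact binomial test, with 28 Fra-1 and 10 Fra-2 peaks (adjusted p = 0.0055). Its Fra-2 peaks were wider, however, with widths that added up to 16000 bp against 13450 bp for Fra-1.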

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

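The split by repeat-like regions, the weighting by width or GC content the test of Fra-1-only peaks against controls and the tests on parts of the repeat-like set were chosen only after peak positions or class shares had been seen.

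Differences between Fra-1-only and Fra-2-only peaks passed tests of the difference itself for several features outside repeat-like regions. As ratios of Fra-1-only to Fra-2-only shares they were 0.535 for TGASTCA, 0.305 for the cyclic AMP response element, 1.81 for TEAD, 1.67 for RUNX, 1.72 for FOXA and 1.46 for GATA. For position they were 0.412 for promoters, 0.334 for coding exons, 0.915 for introns and 1.24 for intergenic sequence. Weighted to the same GC content, the ratios of Fra-2-only to Fra-1-only shares had intervals that included 1 for the cyclic AMP response element (0.783 to 12.1) and for GATA, whose ratio of 0.794 kept the direction of the unweighted 0.683. On chromosome M, 73.7% of the peaks of both lists were Fra-1 peaks.

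The higher TGASTCA and promoter shares of Fra-2-only peaks could reflect technical differences between the lists. A difference in GC content was argued against as the whole cause, since the GC-weighted ratio of TGASTCA shares, Fra-2-only over Fra-1-only, was 1.89 (1.78 to 2.01), although the ratio of promoter shares fell from 2.43 to 1.62 (1.29 to 2.12). That all Fra-2-only peaks were shared-type sites missed near the calling limit of the Fra-1 list was argued against by their promoter share. At matched width it was 2.05 times that of shared Fra-2 peaks (1.71 to 2.42). TEAD was at 0.621 times (0.537 to 0.712) and FOXA at 0.560 times (0.412 to 0.759), while TGASTCA, at 1.22 times, stayed within the range set for that cause. Width only stands in for signal, so closeness to the Fra-1 calling limit was not matched directly, and a part of the set may still be such sites. Calls without a bound site cannot make up the whole Fra-1-only set, whose TGASTCA share was 14.6 times that of controls (11.1 to 19.2), but a part of it may be such calls. With 1 list per antibody, different antibody quality, depth or calling stays open beside a difference between the proteins, which was not tested.

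Repeat-like peaks may come from reads piled up on repeats collapsed in the assembly. Over the whole set TGASTCA was 4.20 times (2.61 to 6.74) as frequent as in controls for Fra-1 and 8.01 times for Fra-2. This met a rule, written before this test, for counting against pile-up. The rule was set aside after parts of the set, tested later, went opposite ways. The set is mixed and its mean decides nothing for all of it. Tandem repeats next to gaps or on chromosome Y made up most of the set. There 6 of 1145 Fra-1 peaks held the element, 0.444 times the control share (0.165 to 1.20). For Fra-2, 8 of 1197 peaks held it, 0.955 times (0.347 to 2.62). Pile-up without a bound site predicted a share at or below that of controls in both lists, and this was met. The prediction was written after the data were seen and other causes could give the same share, so pile-up stays a candidate there. In the other 350 Fra-1 and 394 Fra-2 peaks it was 9.61 times (4.93 to 18.7) and 14.6 times as frequent, which argues against pile-up without a bound site for these as a set. No biological explanation was tested.

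A plain GGAAT repeat does not hold the TEAD consensus, but copies that differ at 1 base can, so its excess could come from diverged satellite copies. Outside repeat-like regions the excess was still 2.21 times the controls for Fra-2 (2.01 to 2.43) and 2.55 times for Fra-1, which argues against that source as the whole cause. Co-occupancy by TEAD factors is a candidate explanation that peak lists of these factors cannot test.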

How the results depend on the processing

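Peaks outside repeat-like regions, wider peaks for the count of genes, 1 member per locus, weighted classes and classes by centre distance were alternatives chosen after seeing the data, and width replaced the missing score in the stricter threshold and the shortened list. No paired analysis was possible because each antibody has 1 list. Of 86 alternative values of the main results, 70 stayed the same: for tested values the direction and side of the threshold, for counts a change of at most 1.5 times. Every alternative for overlap, width, TGASTCA share, promoter share and clustering kept direction and side. Overlap ranged from 67.3% to 82.5% of the Fra-1 list and from 55.8% to 66.8% of the Fra-2 list. Repeat-like peaks taken alone, which are not among these alternatives, overlapped at 85.9% and 79.8%. The intronic share stayed below chance for wider peaks but no longer passed the test (41.4% for Fra-1 and 42.6% for Fra-2), and lay above chance outside repeat-like regions (42.9% and 44.3%), passing for Fra-2 only. The intergenic share of Fra-1 was level with chance among wider peaks (52.3% against 52.4%) and below it outside repeat-like regions (50.6%). For Fra-2, where it did not pass, it passed below chance in both (49.2% and 47.0%), and with promoters of 5 kb it lay below without passing (49.5%). By construction fewer genes were counted within 10 kb (1782 for Fra-1, 2868 for Fra-2), as nearest TSS (4290 and 5492) and, for Fra-1, near wider peaks (5226), all above chance. With nearest TSS only, 8 gene lists passed for Fra-1 instead of 5 and 8 for Fra-2 instead of 6, and ribosomal proteins for Fra-2 had 5 members, below chance; without density matching 4 passed for Fra-2. Lists that passed under neither setting also changed side of chance: for Fra-1 with nearest TSS, HMG (2 members), cell cycle (5), ribosomal (2), neuron (7) and blood cell genes (3), and within 10 kb ribosomal (2) and blood cell genes (1); for Fra-2 cell cycle (6) and blood cell genes (4) with nearest TSS, blood cell genes within 10 kb (3), and HMG (5) and cell cycle genes (5) among wider peaks. Lists that passed under another setting only included basal genes for Fra-2 (nearest TSS, wider peaks, outside repeat-like regions and 1 member per locus), MAPK genes for Fra-1 and AP-1 genes for both factors (10 kb and nearest TSS), TGF-beta genes for both (nearest TSS) and proteases for Fra-2 (nearest TSS). Lists called under every alternative were those of YAP/TAZ-TEAD targets and mesenchymal genes for both factors and of basal genes for Fra-1; the cause of the other changes was not tested. No chromosome departed from the common ratio (0) outside repeat-like regions, which leave out chromosome M, while among wider peaks chromosome 17 did in its place (33.9% Fra-1).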

Other observations

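The tests on CDKN2A below were chosen after its distance had been seen.

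Some long stretches with many genes held no peak of either list. The longest ran on chromosome X from 87859651 to 102893076, over 15 Mb of sequence with 61 protein-coding genes, and the next also lay on chromosome X, from 30301776 to 38742676 with 27 genes including DMD. Copy number of these stretches was not examined. On chromosome 19, a stretch from 19702051 to 29196126 that is rich in zinc finger genes held 41 Fra-1 and 43 Fra-2 peaks, all of them repeat-like. Genes without a peak within 100 kb in either list included SNAI2, a repressor of epithelial genes, KRT5, a basal keratin, ESR1, the oestrogen receptor, and FOS.

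CDKN2A and CDKN2B, cell cycle inhibitor genes on chromosome 9, lay 1287 and 1324 kb from the nearest peak outside repeat-like regions. A gene-poor position is a possible explanation: of protein-coding genes with as few neighbours, 3.83% lay as far away. By a rule written after the distance had been seen, a share under 5% would go against this explanation, and that was met. The pair was picked for its distance, and 5 of 298 list genes lay at least as far as CDKN2A where 5.01 would by the share of all genes. Without chromosome X, where peaks are sparse, 4 of 293 did where 2.22 would (one-sided exact binomial test, p = 0.184), and 1.91% of autosomal genes with as few neighbours lay as far as CDKN2A. The 2 genes share a locus and were selected, so neither count decides and the explanation stays open. Both lie in a stretch of chromosome 9 from 20684801 to 26260476, with 26 protein-coding genes and no peak of either list. Copy number of this stretch in the cell line was not examined, so the lack of peaks is no evidence that binding is absent.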
